A study of Solenopsis invicta with 52 samples.

How the data were processed

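The deposited files hold counts of reads per gene for 52 libraries, 28 from brains and 24 from gasters, with 16314 gene identifiers in the same order in every file. Per the submitters' processing notes, reads were handled with Trim Galore, STAR and edgeR. Their versions, the genome build, the annotation and the alignment settings are not given in the sources used here. Each deposited file gives raw counts in 3 columns, unstranded and for each strand, in the layout of STAR's gene counting. Per the labels' protocols, brain libraries were made from RNA of single brains with a low-input SMARTer kit, which does not mark strand, and gaster libraries with a KAPA stranded kit. In brain the strand columns held equal parts of the counts (49.7% to 50.1% in the reverse-strand column), and the unstranded column was used. In gaster the reverse-strand column held 96.1% to 97.1% of the strand counts and was used. Brain and gaster levels were therefore made with different kits, and only differences between groups within a tissue were compared. A gene that shares reads with a near-identical copy, or in brain with a gene on the opposite strand, is uncertain, since reads that map to several places are left out of these counts and brain counts do not separate strands.

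The 4 rows of each file that name no gene (unmapped, multimapped, no feature, ambiguous) stayed out of library sizes and tests. Unmapped reads made up 6.73% to 29.2% of reads in brain and 11.2% to 53.4% in gaster, multimapped reads 6.38% to 10.3% and 7.68% to 16.3%, and reads in no feature 34.9% to 43.0% and 9.11% to 14.5%. Reads assigned to genes made up 25.3% to 41.6% in brain and 29.1% to 62.4% in gaster. No pair of libraries held identical counts. Groups were taken from the labels of each sample, and per the labels' protocols a stock colony served only once as donor or host within a treatment, so that the workers of a group came from separate colonies.

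Counts were analysed in R 4.3.3 with edgeR 4.0.16. For each tissue, genes were kept by edgeR's filter on expression by group, which left 12006 genes in brain and 11574 in gaster. Libraries were scaled by TMM, and all 4 groups of the tissue entered the same quasi-likelihood fit without covariates. The 4 comparisons per tissue were tested with Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05 with no minimum fold change. The standard errors of log2 fold changes were derived from the F statistic, and their median was 0.166 in brain and 0.185 in gaster. CPM values are relative to the TMM-scaled library, except the summed CPM of gene groups and the individual on and off states, which are relative to all gene counts. The log2 CPM for principal components and outlying libraries used a prior count of 2 and the principal components the 1000 most variable genes. Whether a comparison's effect differed between tissues was tested in a joint fit of all 52 libraries on the unstranded column.

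The rule for named genes, the comparisons and the alternatives were fixed before the data were examined. The rule took, per comparison and tissue, genes past the threshold with a mean log2 CPM above 1, the largest changes in each direction, or, where fewer than 5 genes passed, the 5 with the smallest p. None of the 16314 identifiers matched the table of gene names used here (0 matched), so all counted as uncharacterized and at most 2 in each direction were named. For the same reason the planned gene lists, and the planned test of whether calls lie on the chromosome that carries the supergene, were not run, and Gp-9 was not analysed here.

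The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, a filter of over 1 CPM in at least 6 libraries, a fit of the compared groups alone, surrogate variables (sva 3.50.0, 5 in each tissue), leaving out libraries whose correlation to the others lay over 3 MAD below the median, a covariate for brain libraries whose titles name merged runs, the unstranded column in gaster, and a block for the replicate number. A covariate for individuals numbered under 140, fits within each part of the individuals, and a fit without gaster pBB replicate 1 were added after the libraries had been seen to differ this way.

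Replicate numbers are shared by the groups mBB, pBB and pBL. The brain libraries of pBB and pBL with the same number deviated together from their group means in all 7 pairs (correlation 0.143 to 0.497, mean 0.337, against -0.0557 for other pairs), above the minimum of 0.1 set for each pair, so that these numbers pair the samples. The labels do not say what a number marks. In the gaster pBB and pBL pairs the mean correlation was 0.319, against -0.0631 for other pairs, but the lowest, 0.0928, was under that minimum. Most of these gasters come from the same individuals as the paired brains, so that the pairing taken for brain applies to them too. In the mBB and pBB pairs of both tissues the lowest correlation was under 0.1.

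The tests were checked on simulated counts, drawn independently for each gene and library without differences by individual or replicate number. In each simulation 200 genes were changed by 1.5, 2 or 4-fold. In the brain genotype comparison, over 12006 genes, 47.8%, 77.6% and 89.4% of these genes were recovered, and 5.30% of calls were false. In the gaster genotype comparison, over 11574 genes, the shares were 34.3%, 56.7% and 92.4%, with 1.61% false. In the gaster social form comparison they were 38.8%, 68.7% and 87.9%, with 5.80% false. Splits of the libraries at random were refitted 100 times at most per comparison.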

Results

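RNA-seq read counts were analysed from brains and gasters of single minor workers of the red imported fire ant, Solenopsis invicta. The gaster is the rear part of the abdomen that lies behind the waist. Colonies of this ant are either monogyne, with a single egg-laying queen, or polygyne, with several, and the form follows the haplotypes of a supergene called SB and Sb. Workers with the SB/Sb genotype occur in polygyne colonies, whereas SB/SB workers occur in both forms. Dark pupae were moved into host colonies of 250 workers, and the adults were sampled 16 days later, at 14 to 16 days of age and a body mass of 0.6 to 0.9 mg. Group mBB held SB/SB workers of monogyne origin in monogyne hosts, and group mpBB held SB/SB workers of monogyne origin in polygyne hosts. Group pBB held SB/SB workers of polygyne origin in polygyne hosts, and group pBL held SB/Sb workers of polygyne origin in polygyne hosts. Each group had 7 brain and 6 gaster libraries, which makes 52 libraries from 32 individuals, of which 20 gave both tissues.

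Brain libraries held 14.5 to 70.0 M counts in genes (30.6 ± 12.001 M, SD, n = 28), and gaster libraries held 30.01 to 77.3 M (60.2 ± 9.96 M, SD, n = 24). Group means lay between 27.7 M (pBL) and 35.3 M (mBB) in brain, and between 54.6 M (pBB) and 64.9 M (mpBB) in gaster. Gaster pBB replicate 1 had the lowest gaster total, 30.01 M, and 53.4% of its reads were unmapped, against at most 28.8% in the other gaster libraries. The SB/Sb gasters lay apart from all SB/SB gasters on the second principal component, at 25.2 to 33.6 against -19.3 to 2.35. In brain the pBL range on that component was 8.26 to 29.6 and the range of the SB/SB libraries was -18.7 to 10.8, so that the ranges overlapped. Of the 4 brain libraries whose correlation to the others lay over 3 MAD below the median, 3 were pBL (replicates 2, 4 and 6) and 1 was mBB (replicate 4). Brain pBL replicate 2 also had the most genes with at least 10 counts, 13828 against at most 12744 in the other brains, and lay at 55.5 on the first component. On the first component the gaster libraries differed with the identification number of the individual. The 12 gaster libraries of individuals numbered under 140 had a mean of 15.9 ± 13.2 (SD) and the 12 of individuals numbered over 140 a mean of -15.9 ± 5.70, with overlapping ranges of -9.62 to 29.5 and -23.4 to -2.82. Among those under 140, replicate 8 of mBB, pBB and pBL and mpBB replicate 17 lay at -9.62 to 7.06, and the others at 10.3 to 29.5. The split at 140 leaves this difference out. Each gaster group held 3 libraries of each kind, and each brain group 3 under and 4 over 140.

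**Figure D1:**
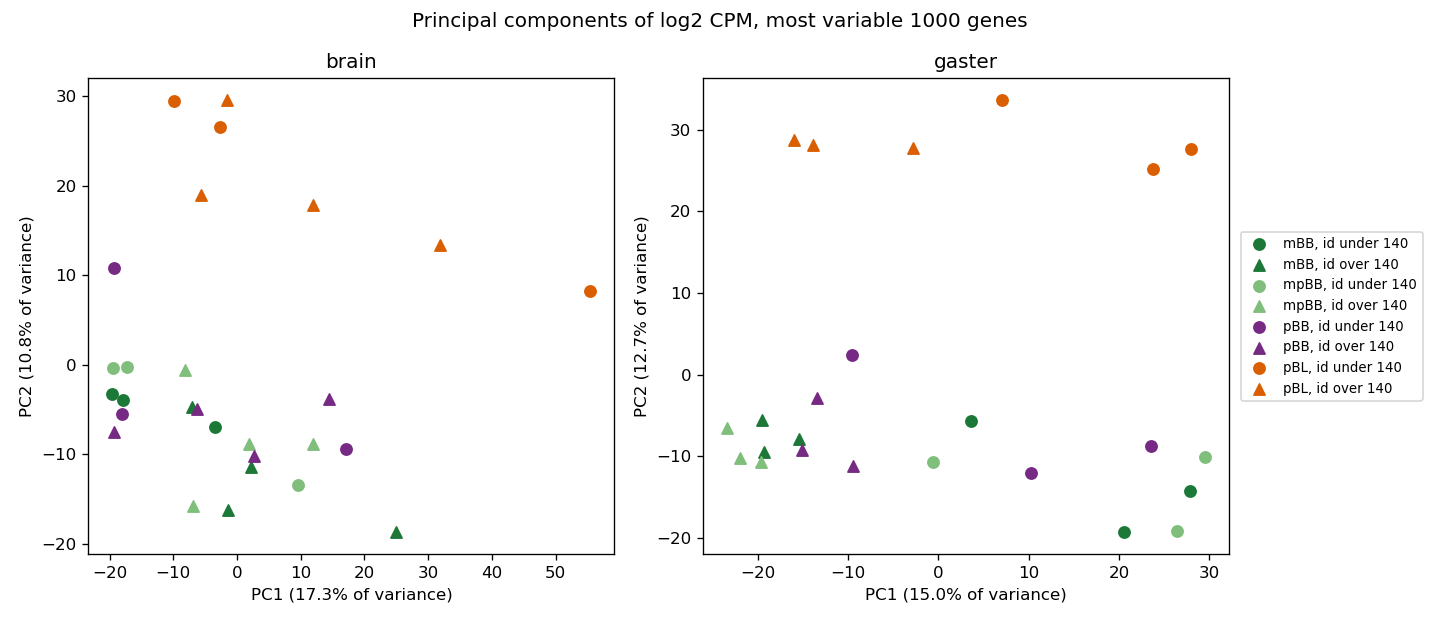
Scores of the brain (left) and gaster (right) libraries on the first (x axis) and second (y axis) principal components of log2 CPM over the 1000 most variable genes; each point is 1 library, colour gives the group and shape the individual number (under or over 140). The pBL gasters lie at 25.2 to 33.6 on the second component, above all other gasters, which lie at -19.3 to 2.35.

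The genotype comparison, pBL against pBB, asked how SB/Sb workers differ from SB/SB workers of the same origin and host form. In brain, 62 of 12006 tested genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 55 higher and 7 lower in SB/Sb workers. Of the 55 higher genes, 30 had a mean under 1 CPM in each of the 3 SB/SB groups, and their median log2 fold change was 4.60. These 30 genes together reached 157 ± 15.2 CPM (SD, n = 7) in pBL brains, against 8.18 ± 2.12 in pBB, 8.89 ± 2.62 in mpBB and 8.00 ± 2.59 in mBB brains (n = 7 each). The lowest pBL brain, at 142 CPM, lay above the highest SB/SB brain, at 13.5 CPM. The genes were chosen on these same libraries for being higher in pBL and under 1 CPM in the SB/SB groups. This separation therefore largely follows from the choice and is no further evidence. Of all 12006 tested genes, 1413 averaged under 1 CPM in each SB/SB group. The distant pBL replicates 2, 4 and 6 were at 142, 183 and 165 CPM, and without the distant libraries 56 genes passed, 47 higher and 9 lower, of which 52 were among the 62. The 25 other higher genes had a median log2 fold change of 1.30 and a range from 0.36 to 4.70. The 7 lower genes had a median of -1.04. The number of lower genes was 13 with the replicate number as a block, which gave 69 genes in all and shared 54 with the 62, and it was 14 with surrogate variables and 15 with DESeq2. The files carry gene identifiers without names, so the genes below are given by identifier only.

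Gene SINVBB1_13081 was at 18.4 ± 3.99 CPM (SD, n = 7) in pBL brains and at 0.0905 ± 0.0606 CPM in pBB brains, with a log2 fold change of 7.63 ± 0.52 (SE) and an adjusted p of 3.38e-11 by edgeR. SINVBB1_01163 was at 19.7 ± 8.54 against 0.236 ± 0.0952 CPM, a log2 fold change of 6.36 ± 0.39 (adjusted p = 3.06e-12). Both were higher in 7 of 7 pBL brains than in every pBB brain. SINVBB1_03520 fell from 43.1 ± 11.2 CPM in pBB to 20.0 ± 5.53 CPM in pBL brains, a log2 fold change of -1.11 ± 0.17 (adjusted p = 0.00015), and lay below every pBB brain in 6 of 7 pBL brains. The other SB/SB brains had 37.1 ± 5.73 CPM of this gene in mpBB and 25.4 ± 4.98 CPM in mBB, so that the mean of mBB lay within the pBL range of 16.4 to 31.5 CPM. SINVBB1_13673 fell from 21.9 ± 3.28 to 10.7 ± 2.83 CPM, a log2 fold change of -1.04 ± 0.19 (adjusted p = 0.00155), below every pBB brain in 7 of 7. Within individuals numbered under 140 alone, with 3 libraries per group, the calls of SINVBB1_03520 and SINVBB1_13673 ended at log2 fold changes of -1.28 (adjusted p = 0.206) and -1.16 (adjusted p = 0.381). Within those numbered over 140, with 4 per group, that of SINVBB1_03520 ended at -0.996 (adjusted p = 0.0755). Over all alternatives the adjusted p ran from 5.03e-08 to 0.206 for SINVBB1_03520 and from 9.93e-06 to 0.381 for SINVBB1_13673.

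In gaster, 69 of 11574 tested genes passed, 58 higher and 11 lower in SB/Sb workers. Of the 58 higher genes, 35 had a mean under 1 CPM in each SB/SB group, with a median log2 fold change of 4.41. SINVBB1_11728, chosen after its values were seen, had 0 counts in pBB gasters. The bound given by 3 counts over that group was a log2 fold change of 6.88. This lies above 4.41, so that setting the gene to the bound left the median at 4.41 by necessity. Together these 35 genes reached 151 ± 32.6 CPM (SD, n = 6) in pBL gasters, against 5.68 ± 0.847 in pBB, 6.43 ± 1.007 in mpBB and 5.82 ± 1.05 in mBB gasters (n = 6 each). They too were chosen on these same libraries, so that this difference largely follows from the choice. In all, 1701 of the 11574 tested genes averaged under 1 CPM in each SB/SB group. SINVBB1_01163, which was also named in brain, was at 10.3 ± 1.51 CPM in pBL gasters and at 0.0332 ± 0.0253 CPM in pBB gasters, where the 6 libraries together held 10 counts, and its log2 fold change was 8.28 ± 0.61 (adjusted p = 7.62e-09). SINVBB1_12864 was at 6.56 ± 2.01 CPM in pBL gasters and at 0.0196 ± 0.0268 CPM in pBB gasters, which together held 5 counts (log2 fold change 8.51 ± 1.79, adjusted p = 0.0182). Its call ended within individuals numbered under 140 alone, with 3 libraries per group, at a log2 fold change of 8.89 (adjusted p = 0.343, against 1.69e-06 to 0.0371 in the other alternatives), and its log2 fold change was 6.25 with counts of both strands and 10.47 with surrogate variables. The gaster of the SB/SB individual mpBB replicate 15 also had 9.58 CPM of this gene. SINVBB1_06378 fell from 61.6 ± 10.1 to 27.1 ± 3.07 CPM, a log2 fold change of -1.18 ± 0.13 (adjusted p = 2.6e-06), below every pBB gaster in 6 of 6 pBL gasters, and its call ended within individuals numbered under 140 alone at a log2 fold change of -1.20 (adjusted p = 0.0565, the highest of the alternatives, whose lowest was 6.39e-16). SINVBB1_07156 was at 0.906 ± 0.291 CPM in pBL and 7.03 ± 7.09 CPM in pBB gasters (log2 fold change -2.95 ± 0.68, adjusted p = 0.0446), lay below every pBB gaster in 2 of 6 pBL gasters, and lost its call in 10 of 13 alternative settings. Without gaster pBB replicate 1 its log2 fold change was -2.48 (adjusted p = 0.134), and with counts of both strands it was -0.96 (adjusted p = 0.108). The other SB/SB gasters had 0.986 ± 0.580 CPM of this gene in mBB and 1.94 ± 1.65 CPM in mpBB, closer to pBL than to pBB.

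**Figure D2:**
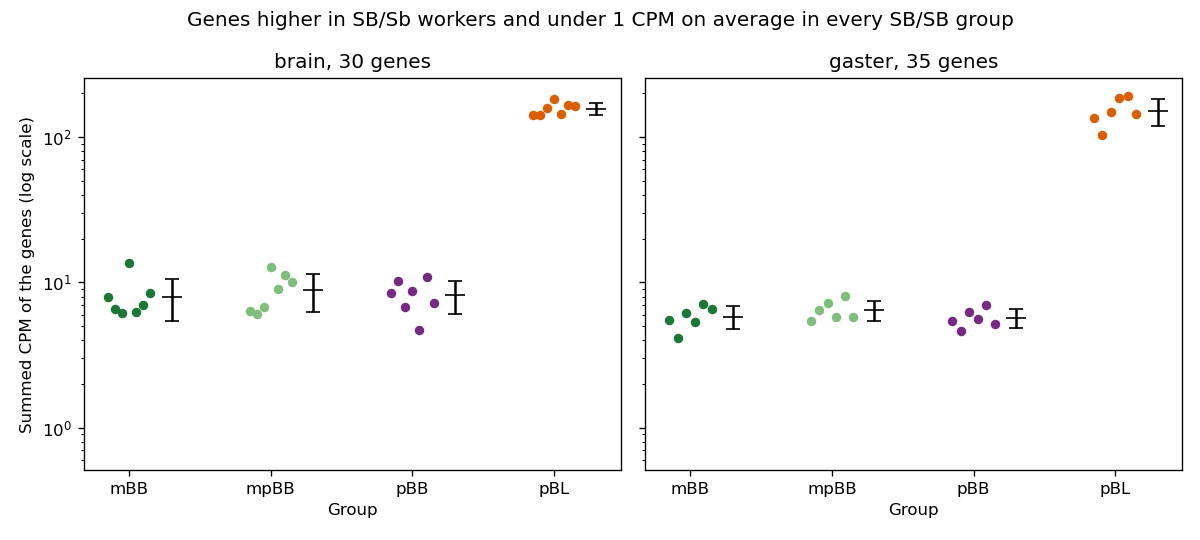
Summed CPM (y axis, log scale) of the genes that were higher in SB/Sb workers and averaged under 1 CPM in every SB/SB group, by group (x axis), for 30 genes in brain (left) and 35 in gaster (right); coloured points are libraries and black marks give the mean ± SD. The pBL brains lie between 142 and 183 CPM and the SB/SB brains between 4.73 and 13.5 CPM. The genes were chosen on these same libraries, so that the separation largely follows from the choice.

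With DESeq2 the gaster count was 108, 87 higher and 21 lower, and it included the 69 genes. Within individuals numbered under 140 alone, with 3 pBL libraries in each tissue, 12 genes passed in brain and 17 in gaster, and within those numbered over 140 the counts were 38 and 34.

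Among the 10661 genes tested in both tissues, 55 were called in brain and 53 in gaster for genotype, and 25 were called in both, where independent lists would share 0.273 (Fisher's exact test, two-sided, p = 8.3e-46). The direction was the same for 24 of the 25 genes. The tissues share 20 individuals, so that the lists are not independent samples of workers. The exception, SINVBB1_01949, was chosen after its values were seen. It was higher in pBL brains (log2 fold change 2.62 ± 0.36, adjusted p = 3.5e-05) and lower in pBL gasters (-0.86 ± 0.15, adjusted p = 0.00261), and the difference between tissues was -3.45 ± 0.34 (adjusted p = 4.1e-10). Within individuals numbered under 140 alone the call of this gene ended in both tissues, at log2 fold changes of 1.98 in brain and -0.98 in gaster, and within those over 140 it ended in gaster, at -0.72. In brain this gene averaged under 1 CPM in each SB/SB group. The genes in the rows right after it, SINVBB1_01570, SINVBB1_06655 and SINVBB1_01566, were also called higher in pBL brains, at 5.16, 4.70 and 2.53. In gaster they did not pass, at -0.149, -0.173 and 0.274. Whether these genes share reads in the unstranded brain counts was not tested. In a joint fit of 13452 genes, the genotype difference itself differed between tissues for 35 genes, 23 of them more positive in gaster and 12 more positive in brain. That fit did not pair the tissues of an individual. With the individual as a block, among the 20 individuals with both tissues, 29 genes passed, of which 27 were among the 35.

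The host colony comparison, mpBB against mBB, asked whether SB/SB workers of monogyne origin differ after adult life in a polygyne rather than a monogyne colony. No gene passed an adjusted p of 0.05 in either tissue by edgeR. In brain 272 of 12006 genes had an unadjusted p under 0.05, where 600.3 would be expected with no differences, and DESeq2 called 1 gene. Random splits of the compared libraries gave a median of 452 such genes. Over the alternatives the number at an unadjusted p under 0.05 ran from 109 to 768, the highest with surrogate variables. In gaster 530 of 11574 genes had an unadjusted p under 0.05, where 578.7 would be expected, and DESeq2 called 0 genes. Random splits of the compared gasters gave a median of 335 such genes, so that the 530 lay above the typical split. The number at an unadjusted p under 0.05 ran from 274 to 830 over the alternatives, the highest with the individual number as a covariate. The gene with the smallest brain p, SINVBB1_14081, was at 23.7 ± 10.0 CPM in mpBB and 10.0 ± 3.52 CPM in mBB brains (SD, n = 7 each) and did not pass (log2 fold change 1.24 ± 0.27, edgeR adjusted p = 0.717), although it passed with DESeq2. SINVBB1_11132 was at 110 ± 11.1 against 78.7 ± 10.8 CPM, a log2 fold change of 0.49 ± 0.11 with the same adjusted p of 0.717, and was higher in 7 of 7 mpBB brains than in every mBB brain. SINVBB1_13889 was at 0.539 ± 0.203 against 1.25 ± 0.462 CPM in brain. In gaster, SINVBB1_01074 was at 20.3 ± 0.947 against 16.2 ± 1.36 CPM and SINVBB1_01001 at 74.2 ± 8.96 against 96.5 ± 10.1 CPM, both with an adjusted p of 0.9999. In counts simulated from the brain libraries for this comparison, over 12006 genes, the same test recovered 29.9% of 1.5-fold, 73.1% of 2-fold and 87.9% of 4-fold changes. In counts simulated from the gaster libraries, over 11574 genes, it recovered 31.3%, 65.7% and 84.8%. Each simulation changed 200 genes at once, which eases the adjusted threshold, and drew each library independently. With fewer changed genes or with variation shared between libraries less would be recovered, so that these shares can be too high for this comparison.

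The overlap of genotype and host colony calls was 0 genes in each tissue and direction, since no gene was called for host colony. At an unadjusted p under 0.01 in both comparisons, 3 genes were higher in both in brain, where independent lists would share 0.472, and 1 in gaster, where 0.546 would be shared. At that level 0 genes were lower in both, and 2 genes in brain and 6 in gaster had opposite directions.

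The origin comparison, pBB against mpBB, asked whether SB/SB workers reared to the pupal stage in polygyne rather than monogyne colonies differ as adults in polygyne hosts. No gene passed by edgeR. Unadjusted p-values under 0.05 were found for 188 of 12006 brain genes and 315 of 11574 gaster genes, where 600.3 and 578.7 would be expected, and DESeq2 called 1 gene in brain and 6 in gaster. Random splits of the compared libraries gave medians of 286 such genes in brain and 330 in gaster. Over the alternatives the numbers at an unadjusted p under 0.05 ran from 175 to 493 in brain, the highest with surrogate variables, and from 251 to 977 in gaster, the highest within individuals numbered over 140. SINVBB1_06613 was at 17.6 ± 20.9 CPM in pBB and 1.44 ± 0.735 CPM in mpBB brains (log2 fold change 3.65 ± 0.74, adjusted p = 0.367), and 3 of 7 pBB brains lay above every mpBB brain. In gaster it was at 3.02 ± 3.06 against 0.367 ± 0.287 CPM (log2 fold change 3.04 ± 0.72, adjusted p = 0.717), again with 3 of 6 pBB gasters above every mpBB gaster. SINVBB1_10666 was at 2.56 ± 1.35 CPM in pBB and 0.762 ± 0.171 CPM in mpBB brains (log2 fold change 1.74 ± 0.40, adjusted p = 0.556), and 7 of 7 pBB brains lay above every mpBB brain. SINVBB1_02469 was at 0.903 ± 0.159 CPM in pBB and 26.9 ± 26.0 CPM in mpBB gasters (log2 fold change -4.90 ± 1.07, adjusted p = 0.717), and SINVBB1_04755 at 1.82 ± 1.17 and 9.25 ± 5.40 CPM (-2.34 ± 0.53, adjusted p = 0.717). With DESeq2, SINVBB1_06613 passed in both tissues and SINVBB1_02469 and SINVBB1_04755 passed in gaster. SINVBB1_05182 was at 0.819 ± 0.400 CPM in pBB and 12.7 ± 29.5 CPM in mpBB brains, the latter mean resting on mpBB replicate 15, at 79.5 CPM.

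The social form comparison, pBB against mBB, set SB/SB workers that differ in both origin and host against each other. In brain no gene passed by edgeR, 497 of 12006 genes had an unadjusted p under 0.05, where 600.3 would be expected, and DESeq2 called 4 genes. Random splits of the compared brains gave a median of 447 such genes, so that the 497 lay above the typical split. Over the alternatives the number at an unadjusted p under 0.05 ran from 323 to 1376, the highest with surrogate variables, which called 1 gene, and it was 846 with the replicate block. SINVBB1_11035 was at 10.98 ± 2.72 CPM in pBB and 4.77 ± 1.95 CPM in mBB brains, higher in 7 of 7 pBB brains than in every mBB brain, and did not pass with edgeR (log2 fold change 1.21 ± 0.24, adjusted p = 0.164) but did with DESeq2. In gaster 7 genes passed, 4 higher and 3 lower in pBB, or 3 higher and 4 lower when scaled by RLE factors. SINVBB1_00481 rose from 110 ± 18.9 CPM in mBB to 185 ± 23.9 CPM in pBB gasters, a log2 fold change of 0.74 ± 0.13. The pBL gasters, which share origin and host form with pBB, had 121 ± 17.2 CPM of it, and mpBB had 132 ± 23.2 CPM. Group pBB thus stood apart, and this gene was also called lower in pBL than in pBB gasters (log2 fold change -0.614). SINVBB1_06374 rose from 11.97 ± 2.19 to 21.1 ± 3.73 CPM, a log2 fold change of 0.82 ± 0.16. SINVBB1_04755 fell from 16.8 ± 5.99 CPM in mBB to 1.82 ± 1.17 CPM in pBB gasters (log2 fold change -3.20 ± 0.55), and SINVBB1_04753 fell from 86.8 ± 27.8 to 26.5 ± 9.46 CPM (-1.71 ± 0.32). These 4 genes had an edgeR adjusted p of 0.0474 each, and in each of them the 6 pBB gasters lay on the same side of every mBB gaster. Their calls held in 5 to 8 of 13 alternative settings. The mpBB gasters, which share the origin of mBB and the host form of pBB, had 9.25 ± 5.40 CPM of SINVBB1_04755. The pBL gasters had 20.2 ± 5.02 CPM of SINVBB1_06374, 5.35 ± 3.51 CPM of SINVBB1_04755 and 38.9 ± 17.5 CPM of SINVBB1_04753.

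The gaster social form count depended on single libraries, on the treatment of the individual number and on other settings. With the replicate block the count was 119, in a fit of the compared groups alone 1, and with no low count filter 0. It was 0 without pBB replicate 1, 23 without mBB replicate 1, 141 (90 higher, 51 lower) with a covariate for individuals numbered under 140, 290 with DESeq2, and 0 within either part of the individuals, with 3 libraries per group. The log2 fold change of SINVBB1_04755 was -3.14 under 140, -3.27 over 140 and -3.10 without pBB replicate 1, and that of SINVBB1_00481 was 0.68, 0.82 and 0.74. With surrogate variables, which also gave 0 genes, the values were -2.01 for SINVBB1_04755 (adjusted p = 0.884) and 0.68 for SINVBB1_00481 (adjusted p = 0.841). Over the alternatives the adjusted p ran from 8.15e-07 to 0.884 for SINVBB1_04755 and from 0.000108 to 0.841 for SINVBB1_00481.

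**Figure D3:**
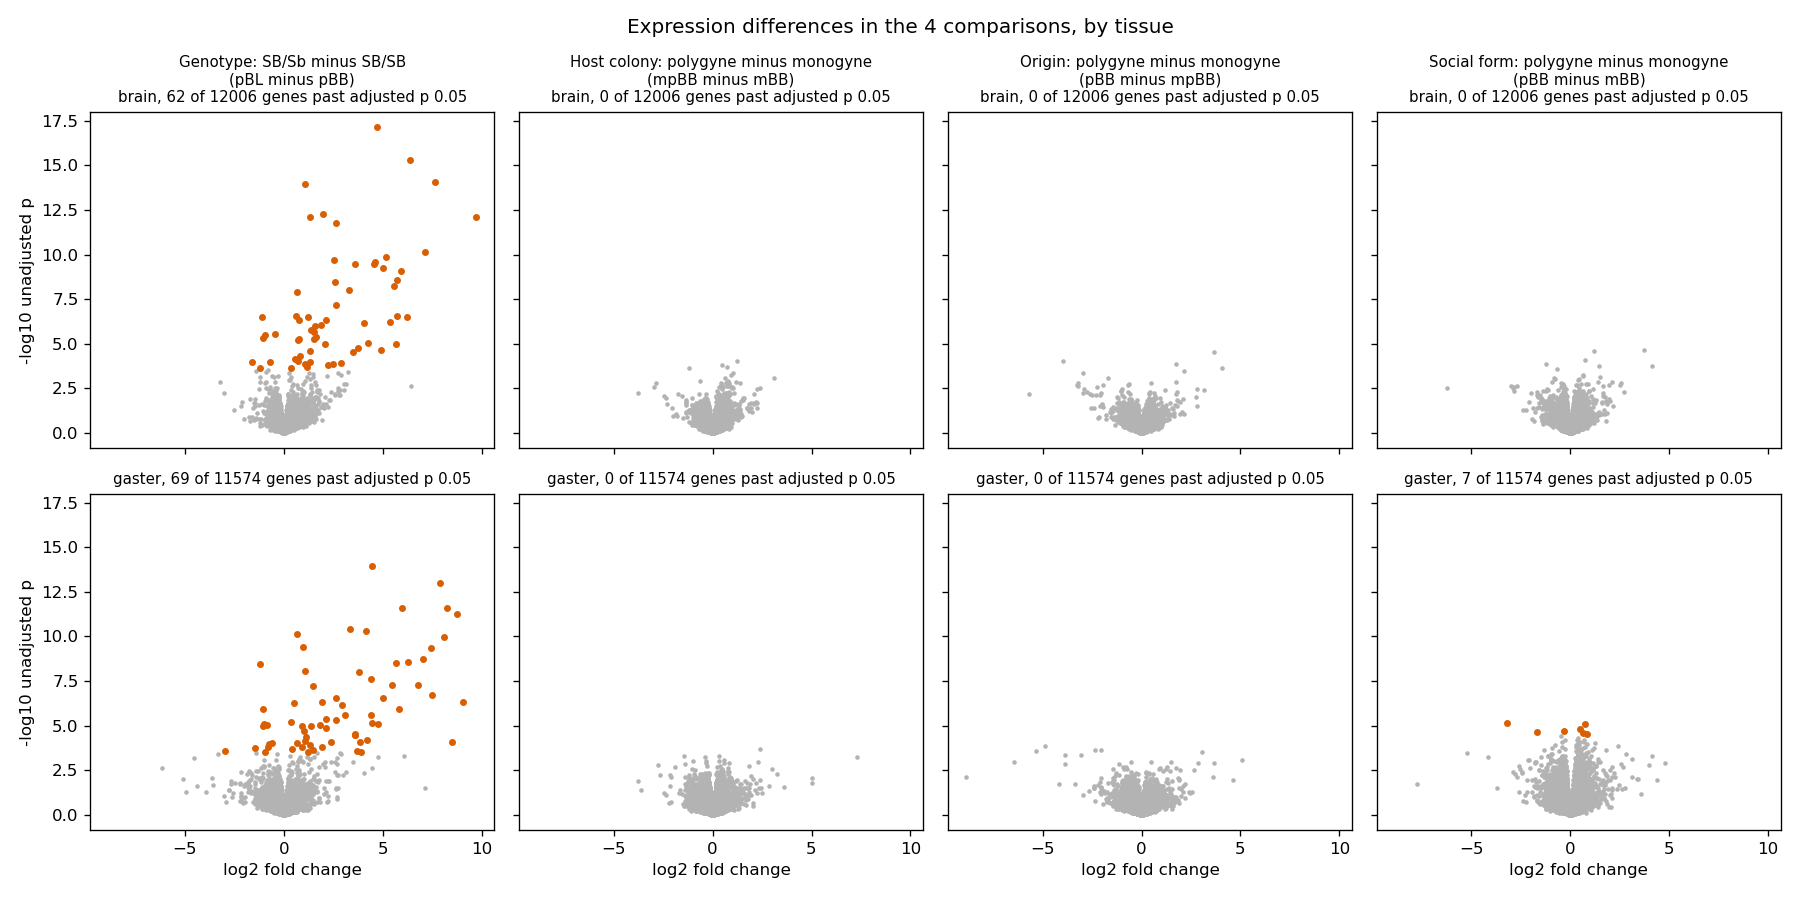
Log2 fold change (x axis) against -log10 of the unadjusted p (y axis) for each tested gene (points) in the 4 comparisons (columns) in brain (top) and gaster (bottom); orange points passed an adjusted p of 0.05. Orange points number 62 and 69 in the genotype panels, 7 in the gaster social form panel and 0 in the other panels.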

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

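The outlying libraries below were found by Dixon's test at the 95% level, which picks out a library in about 5% of groups by chance. Among 69 groups of values tested, 5 had such a library, where 3.45 would by chance. Brain pBB replicate 1 had a log2 CPM of 4.07 for SINVBB1_11035, with the next highest pBB brain at 3.57. Brain mpBB replicate 15 had a log2 CPM of 6.31 for SINVBB1_05182, against 1.58 in the next. Brain pBB replicate 4 had 6.73% unmapped reads, the lowest of its group, against 16.8% in the next. Brain pBL replicate 7 had 44.8 M gene counts against 27.3 M in the next. Gaster pBB replicate 1 had 53.4% unmapped reads against 23.1% in the next pBB gaster.

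Differences between tissues were tested as such in the joint fit. The genotype difference differed between tissues for 35 genes and the social form difference for 1 gene. SINVBB1_03520 was lower in SB/Sb brains, and its genotype difference was 1.37 ± 0.23 (SE) more positive in gaster on the log2 scale (adjusted p = 0.000154). SINVBB1_06378 was lower in SB/Sb gasters, and its difference was -1.58 ± 0.19 in gaster relative to brain (adjusted p = 1.15e-07). SINVBB1_04755 was lower in pBB than mBB gasters, and its social form difference in gaster minus that in brain was -5.25 ± 0.86 (adjusted p = 0.00226).

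The strand column of the gaster libraries that the comparisons did not use held 2.89% to 3.88% of the strand counts. Over the 7916 genes with enough counts in that column, 10 passed for genotype, 8 higher and 2 lower in SB/Sb gasters, of which 3 were also called from the main column. For social form 1 gene passed, which was not called from the main column. The host colony and origin comparisons gave 0 each by edgeR, with 440 and 248 genes at an unadjusted p under 0.05. DESeq2 was not run on that column, and no explanation was tested for these counts.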

How the results depend on the processing

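The individual number settings and the fit without gaster pBB replicate 1 were chosen after the data had been seen, and the other settings before. The genotype counts stayed within 1.5 times of 62 in brain and 69 in gaster, except that DESeq2 called 108 in gaster and that individuals numbered under 140 alone gave 12 and 17 and those over 140 alone gave 38 and 34, fits with fewer samples. With the replicate block the brain genotype count was 69 (56 higher, 13 lower). The gaster count was 71, of which 56 were among the 69 gaster calls. The block changed no other count by over 1.5 times except gaster social form. Own-number correlations were as low as 0.0928 in the gaster pBB and pBL pairs, and 0.0634 in brain and 0.0438 in gaster in the mBB and pBB pairs. In these sets, 5 of 6, 5 of 7 and 3 of 6 samples correlated best with their own number. The mean of the gaster pBB and pBL pairs was nevertheless 0.319, near the 0.337 of the brain pairs. No paired analysis was possible because mpBB shares no number with the other groups for host colony and origin. The counts of 0 became 1 with DESeq2 for brain host colony and for brain origin, 6 with DESeq2 for gaster origin, and 4 with DESeq2 and 1 with surrogate variables for brain social form. The 7 gaster social form calls became 0 with no low count filter, 0 with surrogate variables, 0 within individuals numbered under 140, 0 within those over 140 and 0 without pBB replicate 1, 1 in a fit of the compared groups alone, 11 with the unstranded column, 23 without the distant library mBB replicate 1, 119 with the replicate block (81 higher, 38 lower), 141 with the individual number covariate and 290 with DESeq2. The 7 genes were all among those called with the block, the covariate and DESeq2, and the cause of these changes was not tested. Genes both higher for genotype and host colony rose from 0 to 3 in brain and 1 in gaster at an unadjusted p under 0.01. The genes whose social form difference differed between tissues rose from 1 to 3 with the individual as a block. Over the named genes 308 values kept their direction and side of the threshold, 43 lost and 7 gained significance, and 0 reversed. Many of the 308 belong to genes that did not pass and stayed so, whereas the 43 losses all fall on genes that had passed. The 308 therefore do not measure how stable the calls were. The genes were named for large changes or small p in these same libraries, which makes reversals unlikely from the start. The gene lists and the chromosome test were not run under any setting, since no identifier matched a named gene. Depth limits the genes near 0, of which SINVBB1_11728 had 0 counts in pBB gasters.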

Other observations

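The tests of the individual number, the correlation of individuals between tissues and the splits, except those for gaster genotype and those balanced over the number parts, were fixed before their results were seen. The other tests here were chosen after the pattern had been seen.

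SINVBB1_06613 was high in some SB/SB workers of polygyne origin and low in others, alike in both tissues of each such worker that gave both. In brain, pBB replicates 1, 3 and 5 had 43.6, 33.4 and 42.1 CPM, whereas replicates 2, 4, 6 and 7 had 1.46, 1.37, 0.909 and 0.477 CPM. In gaster, pBB replicates 1, 3 and 5, which come from the same individuals, had 6.93, 5.28 and 5.04 CPM, and replicates 6, 7 and 8 had 0.290, 0.0847 and 0.497 CPM. The 7 pBL brains had 39.9 to 50.7 CPM and the 6 pBL gasters 7.02 to 12.7 CPM. The workers of monogyne origin had at most 2.74 CPM in brain and 0.935 CPM in gaster. SINVBB1_02469 had 13.7 to 65.6 CPM in 3 of 6 mBB and 4 of 6 mpBB gasters, and at most 1.74 CPM in the other gasters, which include the 12 of polygyne origin. In brain it had at most 0.869 CPM in any library, so that this pattern was seen in gaster only.

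Other genes were on or off by individual, at the limits given next. Among genes with at least 3 of the 20 individuals at 1 CPM or more and at least 3 under 0.1 CPM in each tissue, and at most 4 in between, 2 genotype calls were left out and 16 genes remained. In 279 of the 282 pairs of gene and individual with a clear state in both tissues the states agreed, or 98.9%, against at most 95.04% in 10000 shuffles of individuals within group and number part, which averaged 74.2% (permutation p = 1e-04, the smallest they can give). SINVBB1_01214, chosen after its values were seen, was on in both tissues in 9 individuals and off in both in 8, with a mean when on of 10.7 CPM in brain and 51.7 CPM in gaster. Over 10661 genes, an individual's deviation from the mean of its group and number part correlated between brain and gaster with a mean r of 0.252 (0.0531 to 0.372, positive in 20 of 20 individuals), against at most 0.218 in 10000 shuffles (permutation p = 1e-04, the smallest they can give). These correlations are across genes, which are not independent replicates. Neither genetic differences between workers nor carry-over of RNA between the samples of a worker was tested.

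The genotype calls were mostly higher in SB/Sb workers, with many genes near 0 in SB/SB workers. Chance is made unlikely for the counts but is not excluded, since the real split alone is the smallest share these splits can give. In brain 1 of 70 splits of the pBB and pBL libraries gave as many as 62 genes, the real one, and the highest other gave 1. Among 31 splits that part all replicate numbers it was again 1, and the highest other gave 1. In gaster 1 of 100 splits gave as many as 69, and the highest other gave 3. The pBL libraries were on average not deeper than the SB/SB libraries together, with a mean of 87.7% of theirs in brain and 99.3% in gaster. The deepest pBL library had 3.08 and 2.16 times the counts of the shallowest SB/SB library, against median folds of 24.3 and 21.3 for the near-zero genes. This ratio decides nothing, since the folds are of levels already scaled for depth and of genes chosen for being higher in pBL. In gaster the pBL mean of 59.9 M lay above the pBB mean of 54.6 M, and in brain the pBL mean of 27.7 M lay below the pBB mean of 30.2 M.

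The genotype calls also gathered in the order of the files' rows. A window of 1000 rows held 33 of the 62 brain calls and 32 of the 69 gaster calls, against at most 17 in 10000 shuffles in each tissue (permutation p = 1e-04, the smallest they can give), although it held 6.72% and 6.77% of the tested genes. Loss of Sb reads against the reference would lower genes, so that it does not account for the 27 brain and 24 gaster calls there that were higher in SB/Sb workers. It stays open for the lower calls, which lay mostly in the window, 6 of 7 in brain and 8 of 11 in gaster, against 1 lower call among 29 outside it in brain and 3 among 37 in gaster. Most near-zero genes lay outside the window, which held 10 of 30 in brain and 8 of 35 in gaster. Neighbouring rows varied together, with a mean r of 0.111 in brain and 0.0851 in gaster against at most 0.00872 and 0.00839 in 100 shuffles of the rows. The shuffles of calls do not take this into account, and the position of these genes in the genome was not tested.

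A gene near 0 in the other SB/SB workers was on in 1 SB/SB worker. SINVBB1_12864 had 9.58 CPM in the gaster and 1.32 CPM in the brain of mpBB replicate 15, against at most 0.0682 and 0.255 CPM in the 17 and 20 other SB/SB libraries and 4.01 to 8.77 and 0.890 to 4.92 CPM in SB/Sb libraries. Contamination by SB/Sb material would bring the other near-zero genes along, but their median in this worker was 3.04% of the SB/Sb mean in brain and 1.81% in gaster, within the ranges of the other SB/SB libraries, 1.53% to 8.24% and 1.40% to 4.37%. In gaster, 3 of the 35 near-zero genes nevertheless lay over 50% of the SB/Sb mean in this worker, against at most 1 in another SB/SB gaster, and the summed 8.05 CPM of the 35 genes was the highest of the SB/SB gasters. The near-zero genes had to average under 1 CPM in mpBB, this worker included. Genes raised most in it could thus be left out, as SINVBB1_12864 was in gaster, and the medians weigh against contamination only for the genes kept. The medians also argue against a mislabelled SB/Sb worker, since the lowest SB/Sb libraries had 86.1% and 69.4%. A difference between individuals unrelated to genotype stays open, as with the genes that are on or off by individual.

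Individuals numbered under and over 140 differed in 5253 of 11574 genes in gaster and 1867 of 12006 in brain by edgeR, with group in the model. The split at 140 was chosen after the libraries had been seen to differ this way, so that a large gaster count partly follows from the choice. Depth does not account for the difference, since 96.3% and 96.8% of these genes stayed called with depth as a covariate. The difference did not correlate between the tissues of the same individuals beyond shuffled individuals (r = 0.0995 over genes, against -0.201 to 0.187 in 100 shuffles), which is consistent with separate library batches of each tissue, although the labels name no batch and a date, colony or age effect stays open. The number parts are balanced over the groups.

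For host colony and origin in both tissues and for brain social form the real count was 0, which 100 of 100 splits reach by definition, so that the splits decide nothing about these comparisons. The highest other split gave 1 gene, or 0 for brain social form. For gaster social form, 1 of 100 splits gave as many as 7 genes, the real one, and the highest other gave 3. No other split reached the count, but 1 of 100 is the smallest share these splits can give, for 1 of 8 comparisons. The count also fell to 0 without pBB replicate 1, with no low count filter and with surrogate variables. Chance is therefore made less likely for that count but is not excluded. The 1506 genes at an unadjusted p under 0.05 were reached by 7 of 100 splits, the highest other of which gave 2675 and put 6 more libraries of individuals numbered under 140 into a group than into the other. Among the 37 splits balanced over the number parts like the real one, 1 reached 1506, the real one, and the highest other gave 854. No other balanced split therefore reached that number, whereas others among all splits did. Within each number part the social form calls numbered 0.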
